A study of Canis lupus familiaris with 45 samples.

How the data were processed

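Gene expression was measured in subcutaneous adipose tissue of 9 intact female beagles, each sampled after an overnight fast at weeks 0, 4, 8, 12 and 24. The 4 control dogs were fed to maintain body weight, and the 5 ad libitum dogs were fed freely from week 0 on. Total RNA was extracted with Trizol, labelled by the Affymetrix 1-cycle 3' method with biotin and hybridised to canine arrays, 1 array per dog and week, per the labels' protocols. All 45 arrays were used, and none was left out of the comparisons reported first.

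The values deposited by the authors are GCRMA expression values, 1 per probe set, on a scale read here as log2. GCRMA is named in the submitters' processing notes without a version, and the log base, any batch correction and any filter by the authors are not given in the sources used here. The values ran from 0.42 to 17.51, with array medians of 3.60 to 3.83 and a background mode of 2.26, the range that log2 GCRMA values have. Arrays carry no count of molecules, so the number of arrays limits the precision.

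The table held 43035 probe sets, of which 111 were array controls and were left out of the tests. A probe set was tested when its log2 value was above 4 on at least 4 of the 45 arrays, which kept 22690 of 42924 probe sets (52.9%). Gene symbols came from the platform table of the array, and were compared with a RefSeq gene table. Of the tested probe sets, 16915 had 1 symbol, 271 had several and 5504 had none, and the symbols covered 9113 genes. The gene identifiers of 16015 tested probe sets were in the RefSeq table, and 0 symbols needed an update.

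Differential expression was computed in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Every probe set was fitted with 10 means, 1 per feeding group and week, and a term for the laboratory batch in the labels. Batches 1 to 5 mixed weeks 0 to 12 and were coded to sum to 0. Batch 6 held all 9 week-24 arrays and no other, so it had no term of its own. The same 9 dogs, known by the animal id in the labels, were sampled at each week, so the dog was a block with a correlation common to all probe sets, estimated at 0.00562. The fit left 31 residual degrees of freedom. Adjusted p-values are those of limma's moderated test after the Benjamini-Hochberg method over the 22690 probe sets, with a threshold of 0.05.

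The feeding effect at a week is the change from week 0 in ad libitum dogs minus that in control dogs, and the averaged feeding effect is its mean over weeks 4, 8, 12 and 24. A joint test of the 4 weekly feeding effects asked whether the course over time differed between the groups. Direct comparisons of the feeding groups within each week and changes from week 0 within each group came from the same fit. At week 24 the direct comparison and the feeding effect compare groups that share batch 6, whereas a change from week 0 within 1 group is also a change of batch.

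Of 37 gene lists for pathways and cell types fixed before the data were examined, 31 had at least 5 measured genes. The other 6 lists were left out. A list was tested with limma's camera with a preset correlation between genes of 0.01, using for each gene the probe set with the highest mean over the arrays, with Benjamini-Hochberg adjustment over the 31 lists. Camera with an estimated correlation, fry and an exact permutation of each list's mean were run beside it. The permutation took the 126 splits of the 9 dogs into 4 and 5 (smallest possible p 0.00794). Fry and permutation results for lists are not given below. The lists for the feeding effects were planned, and the same tests on the other comparisons were added after seeing the data.

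The genes named in the text follow a rule that was also set before the data were examined, for probe sets with 1 symbol. For the averaged effect it takes up to 12 genes of each sign past the threshold, for each weekly feeding effect up to 4 of each sign, and for each change in ad libitum dogs up to 3 of each sign, by size. Where fewer than 3 pass in a feeding effect, the 3 of each sign with the smallest p are given as values. For each list past the threshold in a feeding effect, it takes the 2 members with the smallest p in the list's direction. LEP, ADIPOQ, FASN, SCD, LPL, PPARG, CCL2 and CD68 are named in any case, at their brightest probe set. After seeing the data the rule was extended to the 8 largest differences of each sign at week 24, 4 of each sign at week 8 and all past the threshold at weeks 4 and 12. Members of lists named beyond this, and the AZGP1 values by batch, were chosen after their values were seen.

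RNA quality was read from the control probe sets as the log2 value of the 3' end minus that of the 5' end of actin and GAPDH, compared between the groups at each week by a 2-sided exact permutation test (10 tests). The identity of each array was checked against the dogs: 100 probe sets that separate the dogs best were chosen on 36 arrays at a time, and each left-out array was correlated with every dog's mean. The fit was tested on simulated data with 200 of 22690 probe sets changed. For the direct comparison at week 24 it recovered 35% of changes of log2 1 and 84% of changes of log2 2, with 7 false calls among 126. The feeding effect at week 24 gave 18% and 59%, with 3 false calls among 80. The change from week 0 in ad libitum dogs at week 24 gave 35% and 83%, with 4 among 122. With no change simulated at week 8 there were 0 limma calls. These rates need not hold for the real arrays.

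The alternatives chosen before the data were examined were no filter, a stricter filter (mean of at least 6), no batch term, no replicate block for the dog, a fixed replicate block for the dog, a further quantile normalization, centring each array on its median, a trended and robust prior, only the arrays of the weeks compared, each dog left out in turn, camera with an estimated correlation, and the mean over all probe sets of a gene. Added after seeing the data were the fit without 10 arrays with skeletal muscle transcripts (mean of the muscle genes above 7), without the week-8 arrays labelled dog 5 and dog 9, without both sets, with the muscle mean as a covariate, and with the actin 3' minus 5' value as a covariate. For chance, 100 splits of the dogs, or of the arrays of the weeks compared, were drawn at random, or all 35 where there were no more.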

Results

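Subcutaneous fat of 9 beagles was measured on 45 arrays, 1 per dog and week. Dogs 1, 3, 4 and 9 were controls fed to maintain body weight (n = 4), and dogs 2, 5, 6, 7 and 8 ate freely, ad libitum, after the week-0 sample (n = 5). Samples at weeks 0, 4, 8, 12 and 24 follow the response of fat to free feeding. The deposited GCRMA values were read as log2, and 22690 probe sets above background were tested. The few dogs limit the precision.

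At week 24, genes that make and store fat were higher in the ad libitum dogs than in the controls. As given below for gene lists, part of this difference was a fall in the control dogs from week 0. SCD, which desaturates fatty acids, was higher by log2 4.30 (SE 0.654, 19.7-fold, adjusted p = 3.09e-04), from 10.21 ± 0.84 (SD, n = 4) to 14.51 ± 0.92 (SD, n = 5). That is 1 of 3 SCD probe sets, and the brightest, with a mean level of 16.12, differed by only 0.72. PNPLA3, a lipid-droplet enzyme induced by carbohydrate feeding, was higher by 4.72 (SE 0.819, 26.3-fold, adjusted p = 0.00150). FITM2, which helps form lipid droplets, was higher by 3.91 (SE 0.689, adjusted p = 0.00166). GPAM, the first enzyme of triglyceride assembly, was higher by 4.03 (SE 0.879, adjusted p = 0.00732). ELOVL6, which lengthens newly made fatty acids, was higher by 4.16 (SE 1.22, adjusted p = 0.0399). PCK1, which supplies glycerol for triglycerides, was higher by 4.83 (SE 1.10, 28.4-fold, adjusted p = 0.00952), from 8.38 ± 0.81 (SD, n = 4) to 13.21 ± 1.36 (SD, n = 5). NPR3, the receptor that clears the lipolytic natriuretic peptides, was higher by 4.24 (SE 0.658, 18.9-fold, adjusted p = 3.86e-04). FAM83A, an adaptor of growth factor signalling, was higher by 4.89 (SE 0.929, adjusted p = 0.00298). LEP, the satiety hormone of fat cells, was higher by 2.70 (SE 0.716, 6.51-fold, adjusted p = 0.0233), from 9.78 ± 1.19 (SD, n = 4) to 12.49 ± 0.69 (SD, n = 5). Control means were 3.02 for FITM2, 3.41 for FAM83A and 3.6 for ELOVL6, below the detection limit of 4, and 4.01 for GPAM, close to it, so no fold is given for them. Each of these genes was higher than the control mean in 5 of 5 ad libitum dogs.

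Among the genes lower at week 24 were CDO1, PTGS1 and PTGDS. CDO1, which breaks down cysteine towards taurine, was lower by a log2 of -3.13 (SE 0.703, adjusted p = 0.00886). PTGS1 (-2.18, SE 0.451, adjusted p = 0.00533) and PTGDS (-2.15, SE 0.609, adjusted p = 0.0338) act in succession in prostaglandin D2 synthesis. CISH, a brake on growth hormone and cytokine signals, stood at -2.12 (SE 0.602, adjusted p = 0.0345), and the transcription factor KLF5 at -2.08 (SE 0.513, adjusted p = 0.0155). ARNTL, the core clock factor also called BMAL1, stood at -2.03 (SE 0.553, adjusted p = 0.0270), PERP, a membrane protein of cell death and adhesion, at -2.07 (SE 0.542, adjusted p = 0.0218), and the phosphodiesterase GDPD2 at -2.01 (SE 0.565, adjusted p = 0.0327). CISH (3.01) and GDPD2 (2.97) were below 4 in ad libitum dogs, so the sizes of these 2 differences are not exact. All 8 were lower in 5 of 5 ad libitum dogs. In all, 1238 probe sets were past the threshold at week 24, 854 higher and 384 lower, for 497 and 182 named genes. The count was 238 without dog 2, 686 without dog 3, 406 without dog 4, 3097 without dog 5, 525 without dog 6 and 505 without dog 7. It was 64 without the 10 arrays that carried skeletal muscle transcripts, which leaves 2 control arrays at week 24. Of the 17 genes named here, SCD (3.83, adjusted p = 0.0412) and CDO1 were past the threshold without these arrays. LEP stood at 2.47 (adjusted p = 0.158), PCK1 at 4.80 (adjusted p = 0.131) and NPR3 at 3.98 (adjusted p = 0.0508). With the actin 3' minus 5' value as a covariate the count was 29. SCD (3.85, adjusted p = 0.0157) and NPR3 (3.66, adjusted p = 0.0256) were past the threshold with it, and LEP stood at 2.26 (adjusted p = 0.298). The SCD probe set with 4.30 was past the threshold in 22 of 22 alternatives, NPR3 in 21 of 22, FAM83A and PCK1 in 19 of 22, GPAM in 17 of 22, LEP in 13 of 22 and ELOVL6 in 9 of 21.

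Among gene lists at week 24, fatty acid synthesis stood highest in ad libitum dogs, with a mean difference of log2 1.28 (SE 0.297) over 18 genes (camera adjusted p = 4.12e-07). Of its genes, 8 were past the threshold over all probe sets and 9 adjusted over the list alone. They included PNPLA3, ELOVL6, SREBF1 (1.67), which switches on lipid synthesis, ACSL1 (1.64), TKT (1.28), SLC25A1 (1.06) and PGD (1.02). Fatty acid uptake, triglyceride synthesis and lipid droplets (23 genes) had a mean of 1.17 (SE 0.281, adjusted p = 6.07e-08), with 7 genes higher over all and 12 higher and 1 lower adjusted over the list alone. They included GPAM, FITM2, DGAT2 (2.37), which makes triglycerides, AGPAT2 (1.71), the glycerol channel AQP7 (2.10) and the droplet coat PLIN2 (0.83). Lipolysis (11 genes) had a mean of 1.01 (SE 0.346, adjusted p = 0.00255). Past both thresholds were 5 of its genes, including hormone-sensitive lipase LIPE (1.77), ABHD5 (1.86) and MGLL (1.04). Adipocyte markers (13 genes) had a mean of 1.16 (SE 0.395, adjusted p = 2.60e-05), with positive values for 13 of 13 genes, 3 past over all and 7 adjusted over the list alone. No list was past the threshold with an estimated correlation (adjusted p = 0.485 for both fatty acid lists, 0.561 for lipolysis and adipocytes). Without the arrays with muscle the camera adjusted p for lipolysis was 0.266. Array means of fatty acid uptake at weeks 0 and 24 were 11.27 and 10.23 in control and 11.3 and 11.4 in ad libitum dogs. Those of fatty acid synthesis were 10.29 and 9.59, against 10.44 and 10.87. The first difference was mainly a fall in control dogs, the second that beside a rise in ad libitum dogs. FASN of this list moved by -1.46 in ad libitum dogs (SE 0.538, adjusted p = 0.104). These changes from week 0 are also changes of batch. PCK1 and NPR3 entered the lists at their brightest probe sets, with 2.39 and 3.39.

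Mitochondrial lists were also higher in ad libitum dogs at week 24. The array means of oxidative phosphorylation fell from week 0 in both groups, from 13.01 to 11.95 in control and from 12.83 to 12.47 in ad libitum dogs. Oxidative phosphorylation had a mean of log2 0.52 (SE 0.192, adjusted p = 1.94e-11), with positive values for 42 of 42 genes. Of these, 3 were past over all (COX8A 0.78, NDUFA4 0.68 and NDUFB6 0.51) and 19 adjusted over the list alone. The citric acid cycle had a mean of 0.62 (SE 0.242, adjusted p = 1.16e-04), with PDHB (1.37) and MDH1 (0.42) past both. Fatty acid oxidation had a mean of 0.57 (SE 0.212, adjusted p = 1.04e-04), with ECI1 (2.61) and ECI2 (1.89) past over all and 8 adjusted over the list alone. Cholesterol synthesis and uptake had a mean of 0.57 (SE 0.188, adjusted p = 0.00943), with INSIG1 (2.29) and CYP51A1 (1.45) past over all and 4 adjusted over the list alone. Lower means were found for complement (-0.56, SE 0.312, adjusted p = 0.00326), fibroblasts and preadipocytes (-0.67, SE 0.393, adjusted p = 0.00255) and skeletal muscle (-2.58, SE 1.94, adjusted p = 0.00220). Limma called 0 of their genes over all, and 3, 0 and 0 adjusted over the list alone. These calls were lost with an estimated correlation: adjusted p = 0.561 for the mitochondrial and cholesterol lists, adjusted p = 0.574 for complement and fibroblasts, and adjusted p = 0.75 for muscle. Without the arrays with muscle the adjusted p was 0.0558 for cholesterol and 0.0823 for muscle, which turned higher there. Cholesterol was also lost with the actin covariate (adjusted p = 0.134) and without dog 2, and lipolysis and muscle without dog 3.

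The other 20 lists were not past the threshold at week 24. Their means were 0.40 for adipokines and secreted adipocyte proteins, 0.39 for insulin signalling and glucose uptake, 0.33 for interferon response, 0.32 for macrophages, 0.18 for angiogenic factors, 0.12 for circadian clock, 0.08 for hypoxia response, 0.06 for adipocyte transcription factors and 0.05 for endothelial cells. They were 0.03 for unfolded protein response, 0.03 for glucocorticoid response, 0.01 for mammary epithelium, -0.02 for cell cycle, -0.08 for T and NK cells, -0.10 for steroid hormone and growth hormone axis and -0.12 for immediate early genes. Means of -0.13 for inflammatory cytokines, chemokines and adhesion molecules, -0.26 for heat shock proteins, -0.32 for collagens and extracellular matrix, and -0.56 for smooth muscle cells and pericytes were the lowest of the 20.

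**Figure D1:**
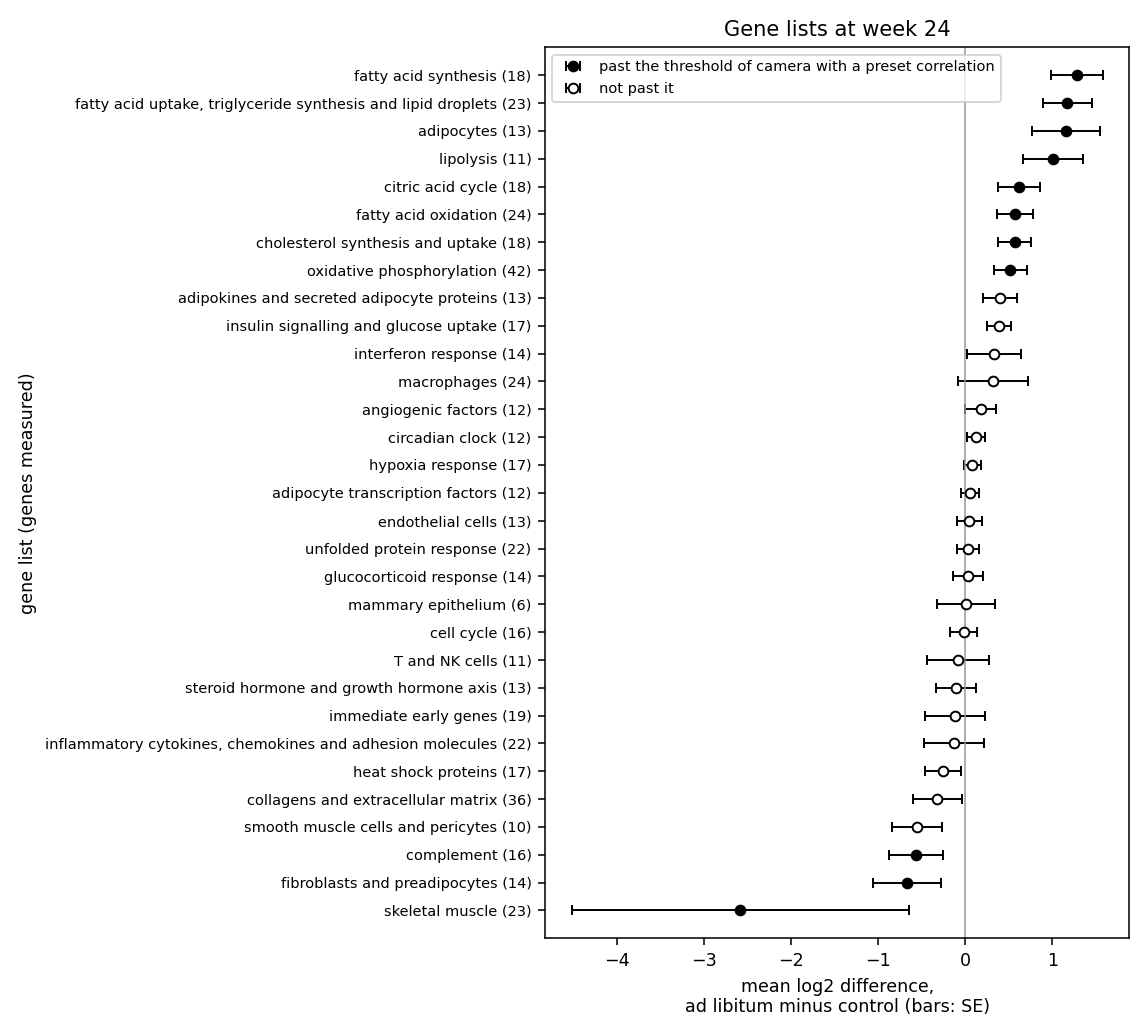
Mean log2 difference between ad libitum (n = 5) and control dogs (n = 4) at week 24 for each gene list on the vertical axis, with the number of genes in brackets and bars of 1 SE. Filled points are past the threshold of camera with a preset correlation, from 1.28 for fatty acid synthesis to -2.58 for skeletal muscle; none is past it with an estimated correlation.

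Skeletal muscle genes separated 10 arrays from the other 35. The mean over 23 contractile and muscle-metabolic genes was 8.45 to 14.74 on these 10 arrays and 4.08 to 6.10 on the other 35. Median levels on the 10 arrays were 17.18 for ACTA1, 15.05 for TNNI2, 14.83 for TNNC2 and 14.51 for MYH2, against 10.34, 1.93, 2.39 and 3.19 on the others. The 10 arrays comprised 5 of 20 control arrays and 5 of 25 ad libitum arrays. Among them were 5 of 9 week-0 arrays, 2 of 4 control arrays at week 24 and none of the 5 ad libitum arrays at week 24. In 43 of 45 arrays, the 100 probe sets that separate the dogs matched the labelled dog. The week-8 array labelled control dog 9 matched ad libitum dog 5 (r = 0.853 across probe sets), and the week-8 array labelled ad libitum dog 5 matched control dog 9 (r = 0.947 across probe sets). Values at week 8 are given as labelled, so each direction at week 8 below includes these 2 arrays under their labels.

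**Figure D2:**
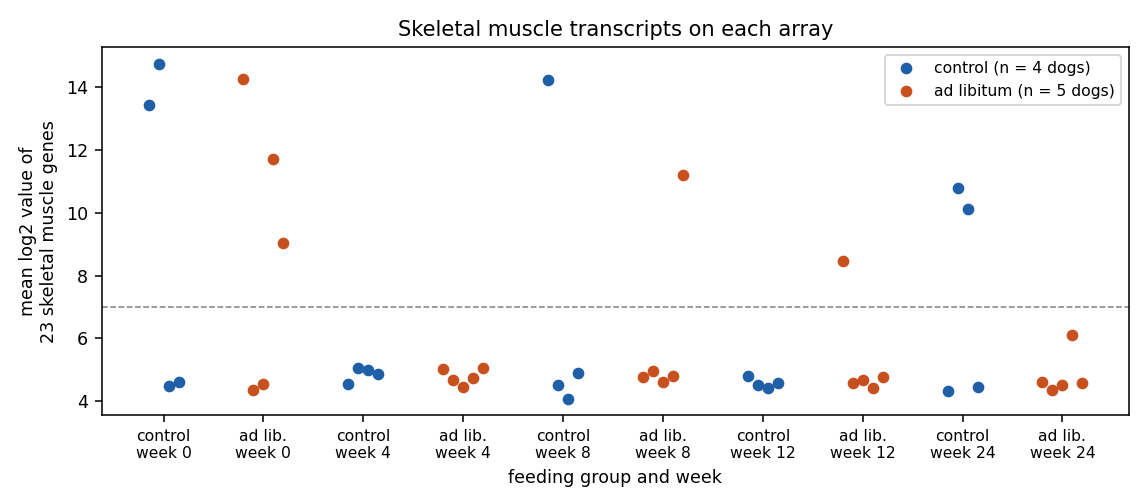
Mean log2 value of 23 skeletal muscle genes on each array, by feeding group and week, with 1 point per dog. The dashed line at 7 separates the 10 arrays with values of 8.45 or more from the 35 with values of 6.10 or less.

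RNA quality was read from the 3' minus 5' value of actin. At week 4 it was 1.75 ± 0.237 (SD, n = 5) in ad libitum and 3.00 ± 0.275 (SD, n = 4) in control dogs (exact permutation p = 0.00794, the smallest possible, adjusted p = 0.0794). The week-4 control arrays lay only in batches 1 and 2, with mean actin values over all weeks of 2.78 and 3.42. The ad libitum arrays lay only in batches 3, 4 and 5, with 1.80, 1.77 and 2.05. The permutation does not take batch into account, so the week-4 difference cannot be told apart from batch. At week 24, beside the fat synthesis genes above, the actin value was 3.51 ± 0.910 (SD, n = 5) and 4.79 ± 1.20 (SD, n = 4; exact permutation p = 0.103). The GAPDH value at week 24 was lower by -0.0741 in ad libitum dogs (exact permutation p = 0.0159, adjusted p = 0.0794). After adjustment 0 of the 10 exact tests was past the threshold, with 2 at an unadjusted p under 0.05.

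At weeks 4, 8 and 12, AZGP1 was higher in the ad libitum dogs. AZGP1 encodes zinc-alpha-2-glycoprotein, a secreted protein tied to lipid mobilisation. It was higher in ad libitum dogs by log2 6.22 at week 4 (SE 0.887, adjusted p = 0.00106, 5 of 5 dogs) and by 4.90 at week 12 (SE 0.814, adjusted p = 0.0191, 5 of 5 dogs). Its control mean at week 4 was 2.35 ± 0.02 (SD, n = 4), which is background. GPLD1, a phospholipase that releases membrane-anchored proteins, was higher at week 4 by 3.00 (SE 0.562, adjusted p = 0.0485, 5 of 5 dogs). SIMC1 stood at -1.71 (SE 0.305, adjusted p = 0.0331, 5 of 5 dogs). The lower group had a mean of 4.03 for GPLD1 and 4.04 for SIMC1, close to 4. Past the threshold were 3 probe sets at week 4 and 1 at week 12. Limma called 0 at week 0, where 312 had an unadjusted p under 0.05. The AZGP1 difference at week 4 was not past the threshold without dogs 3, 8 or 9. At week 4, control arrays lay only in batches 1 and 2 and ad libitum arrays only in batches 3, 4 and 5. Within each of batches 1 to 5, over weeks 4 to 12 together, AZGP1 was 2.47 or less on 12 of 12 control arrays and 6.73 to 10.16 on 14 of 15 ad libitum arrays. The exception was the week-8 array labelled dog 5 at 2.35. Both groups shared a batch at week 8 (batches 1, 3, 4 and 5) and at week 12 (batches 2 and 4), with 1 control array in each and 1 or 2 ad libitum arrays. At week 4 they shared none.

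At week 8, AZGP1 was higher by log2 4.44 (SE 0.754, adjusted p = 0.0144, 4 of 5 dogs), and CSTA, a protease inhibitor, by 2.61 (SE 0.612, adjusted p = 0.0432, 4 of 5 dogs). Control means were 2.38 for AZGP1 and 3.94 for CSTA, below 4, so the sizes are not exact. The array labelled ad libitum dog 5 was the one out of direction for AZGP1. BMP6, a signal of adipocyte and iron metabolism, was higher by 2.22 (SE 0.432, adjusted p = 0.0330, 5 of 5 dogs) and TMEM132C by 2.52 (SE 0.661, adjusted p = 0.0481, 5 of 5 dogs). Lower were the DNA polymerase subunit REV3L (-3.03, SE 0.723, adjusted p = 0.0432) and the deubiquitinase USP25 (-2.60, SE 0.628, adjusted p = 0.0432), each in 5 of 5 dogs. So were the acetyltransferase subunit NAA15 (-2.49, SE 0.651, adjusted p = 0.0481) and TUBGCP5 of the microtubule-nucleating complex (-2.43, SE 0.630, adjusted p = 0.0469), each in 5 of 5 dogs. In all 323 probe sets were past the threshold, 66 higher and 257 lower. The count of 323 became 50 without the arrays labelled dog 5 and dog 9, 2 with the actin value as a covariate and 0 without dog 2. It reached 2067 without dog 7.

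Among lists in the direct comparisons, collagens and extracellular matrix were higher at week 4 (mean log2 0.63, adjusted p = 1.24e-07, 1 gene adjusted over the list alone). So were fibroblasts (0.66, adjusted p = 0.00971) and heat shock proteins (0.47, adjusted p = 0.0377). Camera also called skeletal muscle (fitted mean 2.14, adjusted p = 0.00620), but the array means were 4.78 in ad libitum and 4.86 in control dogs. That call was lost with no batch term, and turned lower without the arrays with muscle (adjusted p = 0.926). Lipolysis was lower (-0.66, adjusted p = 0.0193, 3 genes adjusted over the list alone). At week 12 adipocyte markers (-0.68, adjusted p = 0.0380), fatty acid uptake (-0.40, adjusted p = 0.0474), fatty acid oxidation (-0.39, adjusted p = 0.0212) and oxidative phosphorylation (-0.27, adjusted p = 0.00104) were lower. Complement was higher (0.46, adjusted p = 0.0474). These calls were lost with an estimated correlation, with adjusted p = 0.955 at week 4 and adjusted p = 0.828 at week 12. The lists called at week 4 numbered 1 without dog 1 and 13 without dog 3, and the heat shock call was kept in 14 of 24 alternatives. At week 12 they numbered 0 without dog 1. All but oxidative phosphorylation were also lost there without dog 5 and without the week-8 arrays labelled dog 5 and dog 9 (adjusted p = 0.110 to 0.137). Oxidative phosphorylation (adjusted p = 0.0605) and complement were lost without the arrays with muscle. Camera with the preset correlation also called 0 lists at week 8 and 10 of 31 at week 0, before the feeding change. At week 0 it called 0 with an estimated correlation, and 3 to 18 with 1 dog left out. The week-0 means were values such as 0.26 for fatty acid synthesis (adjusted p = 0.0358) and -0.14 for oxidative phosphorylation (adjusted p = 2.18e-05). Fatty acid synthesis at week 0 turned lower without the arrays with muscle (adjusted p = 0.0674).

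For the feeding effect, the change from week 0 in ad libitum dogs minus that in controls, KIF5A and ARID1A were called at week 24. KIF5A, a kinesin motor, fell relative to controls, with a log2 of -1.29 (SE 0.198, adjusted p = 0.00426, 5 of 5 dogs). So did ARID1A, a subunit of the SWI/SNF chromatin complex, with -1.68 (SE 0.298, adjusted p = 0.0261, 5 of 5 dogs). In total 5 probe sets were past the threshold at week 24, 1 higher and 4 lower, and 2316 had an unadjusted p under 0.05. Not past it at week 24 were KIAA0930 (2.38, SE 0.479, adjusted p = 0.0714) and the lipid-sensing macrophage receptor TREM2 (3.99, SE 0.937, adjusted p = 0.172). Nor were GTF2E1 (1.53, SE 0.358, adjusted p = 0.172) and EXOC4 (-1.41, SE 0.310, adjusted p = 0.169). The joint test over the weeks called AZGP1 (F = 15.6, adjusted p = 0.00303), KIF5A (F = 17.0, adjusted p = 0.00234) and ARID1A (F = 11.6, adjusted p = 0.0368). Their feeding effects were 6.03, -0.10 and -0.63 at week 4 and -0.99, -1.29 and -1.68 at week 24. Without dog 2 the week-24 count was 0, and without dog 8 it was 28. The joint test gave 0 without dog 4 and 2502 without dog 1.

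For the feeding effect averaged over weeks 4 to 24 and at weeks 4, 8 and 12, limma called 0 probe sets, with 959, 1773, 1966 and 1213 at an unadjusted p under 0.05 against 1134.5 by chance. The smallest p values of positive sign in the averaged effect belonged to SLC35G2 (1.51, SE 0.350, adjusted p = 0.418), LOC475806 (0.90, SE 0.220, adjusted p = 0.555) and AZGP1 (3.50, SE 0.873, adjusted p = 0.604). The smallest of negative sign belonged to JARID2 (-1.14, SE 0.222, adjusted p = 0.144), the ether-lipid enzyme AGMO (-2.61, SE 0.511, adjusted p = 0.144) and ZNF333 (-0.96, SE 0.24, adjusted p = 0.604). At week 4 the values were AZGP1 6.03 (SE 1.19), SLC35G2 2.09 (SE 0.475), the collagen-binding FMOD 2.56 (SE 0.663), AGMO -3.77 (SE 0.694), JARID2 -1.50 (SE 0.302) and KIAA1958 -1.69 (SE 0.355). Their smallest adjusted p was 0.111, for AGMO. At week 8, with the arrays as labelled, they were AZGP1 4.25 (SE 1.07), PLPP5 2.10 (SE 0.560), ABR 1.11 (SE 0.298), RNF141 -1.37 (SE 0.268), JARID2 -1.29 (SE 0.271) and DOP1A -2.12 (SE 0.452). Their smallest adjusted p was 0.230. At week 12 they were SLC35G2 2.06 (SE 0.461), AZGP1 4.71 (SE 1.15), LOC489640 4.87 (SE 1.25), AGMO -2.97 (SE 0.674), GPR146 -3.42 (SE 0.827) and ILKAP -1.54 (SE 0.391), all with adjusted p = 0.749.

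The feeding effect at week 24 uses the same week-24 arrays as the comparison above, so its lists are not a second test of it. Fatty acid uptake, triglyceride synthesis and lipid droplets had a mean of log2 1.03 (SE 0.403, adjusted p = 5.46e-06), with DGAT2 at 1.75 (SE 0.466) and PLIN2 at 1.08 (SE 0.314). Fatty acid synthesis had a mean of 1.02 (SE 0.426, adjusted p = 1.76e-04), with PNPLA3 at 3.95 (SE 1.17) and SCD at 0.66 (SE 0.209). Oxidative phosphorylation had a mean of 0.65 (SE 0.275, adjusted p = 1.68e-17) with positive values for 42 of 42 genes, including NDUFA4 at 1.03 (SE 0.299) and NDUFA6 at 0.76 (SE 0.232). The citric acid cycle had 0.76 (SE 0.347, adjusted p = 5.46e-06) with PDHB at 1.43 (SE 0.572) and MDH1 at 0.44 (SE 0.179). Fatty acid oxidation had 0.65 (SE 0.304, adjusted p = 5.20e-05) with ECI2 at 1.88 (SE 0.489) and ECI1 at 2.01 (SE 0.701). Adipocytes had 0.90 (SE 0.566, adjusted p = 0.00370) with LEP at 2.63 (SE 1.02) and AQP7 at 1.94 (SE 0.776). None of these genes was past the threshold over all probe sets. Adjusted over the list alone, 4 of fatty acid uptake, 2 of fatty acid synthesis and 1 of fatty acid oxidation were past it. The calls were lost with an estimated correlation, with adjusted p = 0.522 for the first 5 lists and adjusted p = 0.876 for adipocytes. The adipocyte call was also lost without the arrays with muscle (adjusted p = 0.166).

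Lists in the feeding effect at week 4 were collagens and extracellular matrix at log2 0.69 (SE 0.450, adjusted p = 7.77e-06), with FMOD at 2.05 (SE 0.845) and COL3A1 at 1.46 (SE 0.609). Fibroblasts stood at 0.81 (SE 0.623, adjusted p = 0.00641), with THY1 at 1.56 (SE 0.922). Lipolysis stood at -1.0 (SE 0.548, adjusted p = 0.00296), with the natriuretic peptide receptor NPR1 at -1.43 (SE 0.442) and the protein kinase A subunit PRKAR2B at -2.11 (SE 0.709). Adipocytes stood at -0.73 (SE 0.626, adjusted p = 0.0332), with AQP7 at -1.98 (SE 0.857) and ADIPOQ at -0.61 (SE 0.312). Heat shock proteins stood at 0.66 (SE 0.336, adjusted p = 0.00641), with CRYAB at 3.53 (SE 0.993) and BAG3 at 1.79 (SE 0.742). Skeletal muscle stood at 2.87 (SE 3.07, adjusted p = 8.63e-04), with TTN at 3.35 (SE 1.54) and TCAP at 3.75 (SE 1.95). That muscle call was lost with no batch term, and 2 of 25 alternatives turned it negative, 1 of them past the threshold. Adjusted over the list alone, 2 lipolysis genes and 1 heat shock gene were past the threshold, and none over all. All 6 calls were lost with an estimated correlation, each with adjusted p = 0.818. Without the arrays with muscle the adjusted p was 0.194 for heat shock and adipocytes and 0.812 for muscle. The adipocyte call was kept in 13 of 25 alternatives, and the lipolysis call was lost with no batch term and without dog 1.

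At week 12 the feeding effect on lists was negative for adipocytes (log2 -0.94, SE 0.607, adjusted p = 0.0140), lipolysis (-0.94, SE 0.532, adjusted p = 0.0140), fatty acid uptake (-0.54, SE 0.432, adjusted p = 0.0210) and insulin signalling (-0.46, SE 0.211, adjusted p = 0.0492). Their members included PRKAR2B at -2.14 (SE 0.688), the lipase PNPLA2 at -1.40 (SE 0.625), DGAT1 at -1.33 (SE 0.601), GPD1 at -1.22 (SE 0.546), the insulin-signal kinase AKT2 at -2.52 (SE 0.743) and PFKFB3 at -1.63 (SE 0.528). It was positive for inflammatory cytokines (0.66, SE 0.529, adjusted p = 0.0492), with the monocyte attractant CCL2 at 2.46 (SE 1.37) and VCAM1 at 1.26 (SE 0.685). CCL2 already differed by -1.61 at week 0 and by only 0.86 at week 12 (adjusted p = 0.695), so most of its 2.46 came from week 0. It was also positive for complement (0.60, SE 0.481, adjusted p = 0.0210), with C3AR1 at 1.98 (SE 1.04) and CFI at 1.48 (SE 0.733), and for macrophages (0.55, SE 0.620, adjusted p = 0.0318), with MRC1 at 1.69 (SE 0.908) and LYZ at 1.67 (SE 1.03). The unfolded protein response stood at 0.39 (SE 0.199, adjusted p = 0.0318), with DNAJB9 at 1.64 (SE 0.601) and HSPA5 at 1.34 (SE 0.50). Over all probe sets none of these genes was past the threshold, and adjusted over the list alone 2 insulin signalling genes and 1 lipolysis gene were. All 8 calls were lost with an estimated correlation (adjusted p = 0.818), with a fixed block for the dog, without dog 1 and without dog 5. Camera called 0 lists at week 12 without the week-8 arrays labelled dog 5 and dog 9.

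Averaged over the weeks, oxidative phosphorylation had a mean of log2 0.19 (SE 0.224, adjusted p = 3.05e-04) with positive values for 36 of 42 genes, including NDUFA4 at 0.60 (SE 0.244) and NDUFA6 at 0.41 (SE 0.189). Compared directly, this list was lower in ad libitum dogs at weeks 0 and 12 and higher at week 24. Part of the 0.19 thus came from week 0. Macrophages had 0.54 (SE 0.470, adjusted p = 0.00357), with the secreted phosphoprotein SPP1 at 3.14 (SE 1.42) and SIGLEC1 at 0.58 (SE 0.362). Both calls were lost with an estimated correlation (adjusted p = 0.812), and limma called 0 of their genes over all or over the list alone. The first was also lost without dogs 2 or 3, and in 1 of 24 alternatives was past the threshold in the negative direction. The macrophage call was kept in 17 of 24 alternatives. It was lost with no batch term, without dogs 1, 4, 5 or 8, and without the week-8 arrays labelled dog 5 and dog 9 (adjusted p = 0.0776). At week 8 camera called 0 of 31 lists.

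From week 0 to week 4 the ad libitum dogs gained AZGP1, ELOVL6 and leptin expression. AZGP1 rose by log2 6.04 (SE 0.765, adjusted p = 8.40e-05), from 2.31 ± 0.05 (SD, n = 5) to 8.26 ± 1.21 (SD, n = 5). ELOVL6 rose by 5.84 (SE 1.25, adjusted p = 0.0189), the thyroid and growth axis protein IGSF1 by 4.78 (SE 1.10, adjusted p = 0.0355) and LEP by 2.99 (SE 0.730, adjusted p = 0.0498). AGMO changed by -3.86 (SE 0.626, adjusted p = 9.47e-04), the purine oxidase XDH by -2.15 (SE 0.505, adjusted p = 0.0381) and the glycolysis regulator PFKFB1 by -1.97 (SE 0.442, adjusted p = 0.0280). All 7 moved in the same direction in 5 of 5 dogs, and 113 probe sets were past the threshold, 81 higher and 32 lower. At week 0 AZGP1 was at background and ELOVL6 (3.34 ± 0.34, SD, n = 5) and IGSF1 (3.38) below 4, as was AGMO at week 4 (3.22), so the sizes of these changes are not exact. LEP was past it in 8 of 23 alternatives and AZGP1 in 22 of 22. The count ran from 23 without dog 5 to 1966 without dog 8.

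At week 8, with the array labelled ad libitum dog 5 under its label, IGSF1 rose by log2 6.23 (SE 1.08, adjusted p = 0.00520), LOC489231 by 4.21 (SE 0.798, adjusted p = 0.00801) and LEP by 3.39 (SE 0.714, adjusted p = 0.0103), each in 5 of 5 dogs. AZGP1 rose by 4.41 (SE 0.748, adjusted p = 0.00476), but was at background on the array labelled dog 5 (2.35), as that dog was at week 0. CCDC18 (-3.78, SE 0.936, adjusted p = 0.0194), the bone and matrix protein OMD (-3.28, SE 0.909, adjusted p = 0.0304) and SLITRK6 (-3.12, SE 0.815, adjusted p = 0.0242) fell, each in 4 of 5 dogs. CCDC18 (4.0) was at the detection limit at week 8 and SLITRK6 (3.31) below it, as IGSF1 was at week 0. Past the threshold were 1527 probe sets, 659 higher and 868 lower. With each array centred on its median, which shifts the median of all probe sets by 0.103, the calls were 909 higher and 766 lower. The count was 617 without the arrays labelled dog 5 and dog 9, 12 without dog 2 and 5814 without dog 8.

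At week 12 AZGP1 rose by log2 5.17 (SE 0.730, adjusted p = 4.33e-04), ELOVL6 by 5.02 (SE 1.19, adjusted p = 0.0354) and the Wnt-binding carboxypeptidase CPZ by 4.41 (SE 0.961, adjusted p = 0.0204). G6PC1, the last enzyme of glucose release, changed by -4.48 (SE 1.13, adjusted p = 0.0491), ASB2 by -3.83 (SE 0.709, adjusted p = 0.00645) and LOC483462 by -2.94 (SE 0.593, adjusted p = 0.0118). At week 24 the collagen cross-linker LOX rose by 5.27 (SE 0.808, adjusted p = 2.47e-04), ELOVL6 by 4.29 (SE 1.17, adjusted p = 0.0304), NPR3 by 3.98 (SE 0.632, adjusted p = 3.54e-04) and LEP by 3.53 (SE 0.688, adjusted p = 0.00345). ASB2 changed by -4.28 (SE 0.972, adjusted p = 0.0101) at another probe set, LOC483462 by -4.16 (SE 0.585, adjusted p = 8.75e-05) and G6PC1 by -3.69 (SE 1.12, adjusted p = 0.0491). All were in 5 of 5 dogs. G6PC1 was below 4 at weeks 12 (2.60) and 24 (3.64), as AZGP1 and ELOVL6 were at week 0, so their sizes are not exact. Past the threshold were 182 probe sets at week 12 (93 higher, 89 lower) and 1084 at week 24 (540 higher, 544 lower). All week-24 arrays were in batch 6, from which the change at week 24 cannot be told apart. LOX and LOC483462 at week 24 and AZGP1 at week 12 kept their calls in each of the 22 or 23 alternatives, G6PC1 in 5 of 22 at week 12 and 6 of 22 at week 24. The count without dog 6 was 2 at week 12 and 91 at week 24, where LEP was no longer past the threshold.

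**Figure D3:**
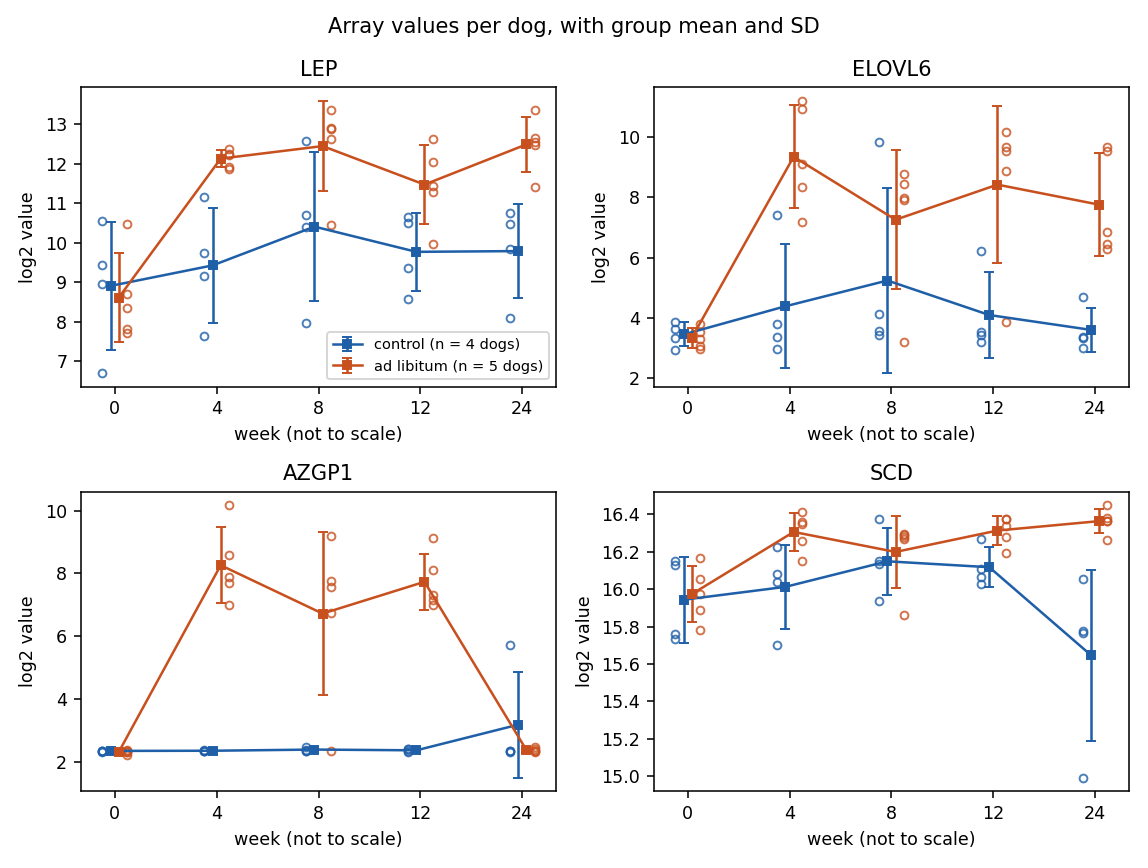
Log2 array values of LEP, ELOVL6, AZGP1 and SCD (brightest probe set) against week, with 1 circle per dog and squares and bars for the mean and SD of the control (n = 4) and ad libitum dogs (n = 5), week 8 as labelled. AZGP1 in ad libitum dogs was 8.26 at week 4, 7.73 at week 12 and 2.37 at week 24, while LEP was 12.13 at week 4 and 12.49 at week 24.

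Lists in the ad libitum dogs changed most at week 12, where 19 were past the threshold. T and NK cells rose by a mean of log2 1.21 (SE 0.345, adjusted p = 2.45e-07), with positive values for 11 of 11 genes. The cytotoxic genes GZMK (2.19) and NKG7 (1.40) were past over all, and 8 were past adjusted over the list alone. Collagens rose by 0.82 (SE 0.277, adjusted p = 6.32e-10), with LOX (3.65) and ADAMTS2 (1.52) past over all and 17 higher and 2 lower adjusted over the list alone. Inflammatory cytokines rose by 0.91 (adjusted p = 2.76e-04) with the T-cell attractant CCL5 at 3.83. Fibroblasts (0.98), complement (0.63), macrophages (0.62), adipokines (0.58), interferon response (0.53) and the unfolded protein response (0.32) also rose. Glucocorticoid response (-0.57, adjusted p = 2.74e-04) and insulin signalling (-0.51, adjusted p = 7.10e-04) fell with PDK4 (-1.40), the brake on glucose oxidation. So did lipolysis (-0.59), adipocytes (-0.59), fatty acid uptake (-0.49), adipocyte transcription factors (-0.46), fatty acid oxidation (-0.45), the citric acid cycle (-0.33), oxidative phosphorylation (-0.28) and skeletal muscle (-3.74). All 19 calls were lost with an estimated correlation. Adjusted p was 0.159 for T and NK cells, 0.260 for collagens, 0.344 for inflammatory cytokines and 0.158 for both glucocorticoid response and insulin signalling. Without the arrays with muscle, oxidative phosphorylation, the citric acid cycle, fatty acid oxidation, the unfolded protein response and muscle were not past the threshold (adjusted p = 0.232, 0.920, 0.205, 0.205 and 0.232). Oxidative phosphorylation, the citric acid cycle and muscle turned positive there. Without dog 8 the 19 lists fell to 10, and lipolysis, adipocytes, inflammatory cytokines and complement were among those lost. The call for adipocyte transcription factors was kept in 15 of 25 alternatives. T and NK cells and collagens also rose in control dogs at week 12, and neither was called in the feeding effect at that week.

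At week 4 in ad libitum dogs, fatty acid synthesis rose by a mean of log2 0.62 (SE 0.303, adjusted p = 0.0166; ELOVL6 past over all, 3 genes adjusted over the list alone). Collagens rose by 0.50 (SE 0.290, adjusted p = 1.21e-05), with FMOD (2.94), ADAMTS2 (1.64), COL4A1 (0.92) and COL4A2 (0.89) past over all and 8 higher and 1 lower adjusted over the list alone. At week 24 collagens rose by 0.39 (adjusted p = 0.0408) and heat shock proteins by 0.57 (adjusted p = 0.00806). Oxidative phosphorylation fell, with a mean of -0.36 (SE 0.185, adjusted p = 1.42e-05), NDUFV1 at -0.90 and NDUFS1 at -0.67. Skeletal muscle genes stood at -2.86 (SE 1.98) at week 4 and -3.62 at week 24. The calls were lost with an estimated correlation (adjusted p = 0.675 at week 4 and 0.929 at week 24). The 3 lists at week 4 were 0 without dog 8 and 11 without dog 4. Without the arrays with muscle oxidative phosphorylation at week 24 had adjusted p = 0.822, and collagens and heat shock proteins adjusted p = 0.0616. Muscle turned positive there at both weeks. The collagen call at week 24 was kept in 12 of 25 alternatives, and lost with the muscle (adjusted p = 0.232) and actin covariates (0.0754). At week 8 camera called 0 lists. Fatty acid synthesis rose more in control dogs at week 4 and was not called in that feeding effect.

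In control dogs, mitochondrial genes were lower at week 24 than at week 0. Oxidative phosphorylation had a mean of log2 -1.01 (SE 0.204, adjusted p = 1.02e-33) with negative values for 42 of 42 genes. Of these, 37 were past over all, among them NDUFS8 (-1.79), NDUFA9 (-1.42), SDHC (-1.34) and SDHD (-1.31). The citric acid cycle was lower (-0.83, adjusted p = 2.59e-07), with IDH3B at -1.40, SDHB at -1.31 and SUCLG1 at -1.22, and so was fatty acid oxidation (-0.76, adjusted p = 5.19e-06), with ECI1 at -1.87 and BDH1 at -1.49. Fatty acid uptake was lower (-1.01, adjusted p = 2.49e-06), with FITM2 at -3.39, DGAT1 at -1.96 and DGAT2 at -1.61. Fatty acid synthesis was lower (-0.69, adjusted p = 0.0115), with THRSP at -3.33 and FASN at -1.85, as were adipocytes (-0.70, adjusted p = 0.0199). Collagens (0.66, adjusted p = 1.35e-04), fibroblasts (0.74, adjusted p = 0.0132), heat shock proteins (0.64, adjusted p = 0.00139) and immediate early genes (0.43, adjusted p = 0.0403) were higher, with HSPH1 at 2.85 and KLF6 at 1.45. The calls were lost with an estimated correlation. Adjusted p was 0.379 for oxidative phosphorylation, 0.440 for the citric acid cycle, fatty acid oxidation and uptake, and 0.837 for fatty acid synthesis. Without the arrays with muscle, fatty acid synthesis (adjusted p = 0.106), collagens (0.134), adipocytes (0.257) and fibroblasts (0.348) were lost, and all 4 were lost without dog 3. With the actin covariate fatty acid synthesis (adjusted p = 0.102), adipocytes (0.508), fibroblasts (0.141) and immediate early genes (0.145) were lost. Past the threshold were 1797 probe sets at week 24, 728 higher and 1069 lower. The change of batch from week 0 to batch 6 cannot be told apart from the change with time. The count was 23 without the arrays with muscle, which include 2 of 4 control arrays at each of weeks 0 and 24. It was 140 without dog 3. With actin 3' minus 5' as a covariate it was 8, and the actin value in control dogs was 2.89 at week 0 and 4.79 at week 24. At weeks 4, 8 and 12 limma called 1, 0 and 0 probe sets, with 5470, 322 and 4029 at an unadjusted p under 0.05.

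Camera called 3, 9 and 5 lists in control dogs at weeks 4, 8 and 12. At week 4 fatty acid synthesis (0.87, SE 0.328, adjusted p = 0.00700) and cholesterol synthesis and uptake (0.69, SE 0.208, adjusted p = 0.00392) rose. Skeletal muscle (-5.73, SE 2.14, adjusted p = 1.45e-11) fell. At week 8, as labelled, fatty acid synthesis (0.54, adjusted p = 3.84e-06), cholesterol synthesis (0.35, adjusted p = 2.02e-04), lipolysis (0.32, adjusted p = 0.0380) and adipocytes (0.31, adjusted p = 0.0241) rose. Macrophages (-0.67, adjusted p = 4.52e-08), complement (-0.49, adjusted p = 6.95e-05), fibroblasts (-0.35, adjusted p = 0.00229), cell cycle (-0.30, adjusted p = 7.20e-05) and muscle (-2.23, adjusted p = 2.04e-06) fell. At week 12 T and NK cells rose by 1.04 (SE 0.397, adjusted p = 0.00131), with positive values for 11 of 11 genes, and collagens by 0.55 (SE 0.319, adjusted p = 0.00658). Oxidative phosphorylation (-0.15, adjusted p = 0.0245), the citric acid cycle (-0.46, adjusted p = 0.0186) and muscle (-4.17, adjusted p = 4.81e-07) fell. All these calls were lost with an estimated correlation, each with adjusted p of 0.410 or more. The 5 calls at week 12 were lost when the arrays with muscle were left out (adjusted p = 0.762 or more). So were fatty acid synthesis at weeks 4 and 8 (adjusted p = 0.25 and 0.0599), lipolysis (0.772), adipocytes (0.985), fibroblasts (0.496) and cell cycle (0.0809) at week 8, and muscle, which turned higher, at weeks 4 and 8 (adjusted p = 0.433 and 0.772). Lipolysis (adjusted p = 0.101), adipocytes and fibroblasts (both 0.107) at week 8 were also lost without the arrays labelled dog 5 and dog 9, as was oxidative phosphorylation at week 12 (adjusted p = 0.114).

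Of the 8 genes named in any case, LEP and SCD differed at week 24. LEP stood at 8.90 ± 1.62 (SD, n = 4) in control and 8.61 ± 1.12 (SD, n = 5) in ad libitum dogs at week 0. Its differences at weeks 4, 8 (as labelled) and 12 were 2.00 (SE 0.846, adjusted p = 0.496), 2.07 (SE 0.720, adjusted p = 0.0883) and 1.62 (SE 0.777, adjusted p = 0.452). SCD at its brightest probe set was higher by 0.72 at week 24 (SE 0.146, adjusted p = 0.00505, 5 of 5 dogs). The other 6 were not past the threshold in any comparison of the feeding groups. At week 24 their differences were 0.35 for adiponectin, ADIPOQ (SE 0.198, adjusted p = 0.301), 0.66 for fatty acid synthase, FASN (SE 0.561, adjusted p = 0.513), and 0.79 for the adipogenic factor PPARG (SE 0.399, adjusted p = 0.236). They were -0.31 for CCL2 (SE 0.892, adjusted p = 0.877) and 0.33 for the macrophage marker CD68 (SE 0.661, adjusted p = 0.815), and 0.35 for lipoprotein lipase, LPL. Averaged feeding effects were 2.03 for LEP (SE 0.833), 2.35 for CCL2 (SE 1.04; -1.61 at week 0), 0.24 for SCD (SE 0.170), -0.30 for ADIPOQ (SE 0.230), -0.56 for FASN (SE 0.652), -0.18 for LPL (SE 0.414), -0.19 for PPARG (SE 0.465) and -0.14 for CD68 (SE 0.769), none past the threshold.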

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

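Chosen after the results were seen were the tests of the arrays with muscle, week-8 identity and week-24 difference, and AZGP1 values by batch. The splits of the dogs and the RNA quality probes were planned.

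Single arrays stood far from the rest of their group, measured by the gap to the nearest other array over the group's range, in 16 of 130 groups of 4 or 5 arrays over 13 measures. Chance gives about 1 in 20 groups, or 6.5. ELOVL6 was 9.83 on the array labelled control dog 9 at week 8 (other controls 3.44 to 4.12) and 3.19 on the array labelled ad libitum dog 5 at week 8 (others 7.92 to 8.77). LEP on the array labelled ad libitum dog 5 at week 8 was 10.45 (others 12.62 to 13.36) and SCD there 15.86 (others 16.27 to 16.30). AZGP1 was 2.47 on the array labelled control dog 9 at week 8 (others 2.35 to 2.37) and 5.71 in control dog 4 at week 24 (others 2.32 to 2.35). ELOVL6 was 6.23 in control dog 1 at week 12 (others 3.20 to 3.52) and 3.86 in ad libitum dog 7 at week 12 (others 8.88 to 10.18).

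Ad libitum dog 5 stood low at week 24 for ADIPOQ (14.72, others 15.77 to 15.96) and PPARG (10.97, others 12.76 to 12.99). LPL was 14.52 in ad libitum dog 2 at week 12 (others 13.62 to 13.74), and PPARG was 13.35 in control dog 1 at week 12 (others 11.54 to 11.82). The mean of the skeletal muscle genes was 14.24 in control dog 4 at week 8 (others 4.08 to 4.89). In ad libitum dog 7 it was 11.2 at week 8 (others 4.60 to 4.97), 8.449 at week 12 (others 4.41 to 4.77) and 6.105 at week 24 (others 4.34 to 4.61).

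The feeding difference at week 24 was tested against that at week 4. For AZGP1 it moved by -7.02 (SE 1.16, limma adjusted p = 0.0172 over all probe sets), from 6.22 at week 4, higher in 5 of 5 dogs, to -0.81 at week 24. In batch 6 AZGP1 was 2.32 to 2.47 on 5 ad libitum arrays. It read above background on 1 array, control dog 4 (5.71), which carried muscle (10.13) and had the highest actin value of all (5.86). For KIF5A it moved by -1.19 (SE 0.214, limma adjusted p = 0.0378), from -0.03 to -1.22, lower in 5 of 5 dogs at week 24. Over all probe sets 2 moved past the threshold. Batch 6 is common to both feeding groups at week 24, and the cause of these shifts was not tested.

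The first pattern weighed is skeletal muscle transcripts on 10 of the 45 arrays. Against a laboratory batch as the source, the 10 arrays lay in 5 of the 6 batches, and against ad libitum feeding, 5 of the 10 were taken at week 0, before the feeding change. Skeletal muscle caught in the sampled fat is a candidate source: on these arrays ACTA1 had a median of 17.18, TNNI2 15.05, TNNC2 14.83 and MYL1 14.71, against 10.34, 1.93, 2.39 and 2.46 on the others. Of the 23 list genes, 9 had a median above 4 on the other 35 arrays, so fat expresses them too, and 0 were held by another list. In a second set of 17 muscle genes, 12 (70.6%) were higher on all 10 arrays than the median of the others, fewer than the 80% set as the mark. Those that missed it were LDB3 (lowest of the 10 arrays 1.831, median of the others 1.839), MYOZ2 (2.164 and 2.181), CACNG1 (2.205 and 2.218), COX6A2 (3.596 and 3.602) and TRDN (4.465 and 4.554). All but TRDN were below 4 there, so the mark decides little for them. A higher median was found for 17 of 17, by 1.98 to 9.64, and muscle in the fat stays a candidate source.

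The second pattern is the pair of week-8 arrays whose dog-specific probe sets match another dog. Poor RNA or muscle as the cause is argued against by 10 of 10 arrays with muscle that matched their own dog, and by actin values of 1.72 and 1.98 on the pair, within the 1.35 to 3.12 of the other week-8 arrays. The array labelled control dog 9 matched dog 5 (r = 0.853 across probe sets, own dog -0.160), and the array labelled ad libitum dog 5 matched dog 9 (r = 0.947, own dog -0.194), also over the next 100 probe sets, where 41 of 45 arrays matched their dog. An exchange of the 2 samples or their labels may explain both matches, and every direction at week 8 rests on the labels as given. AZGP1 was at background on both arrays (2.47 and 2.35), while dog 5 read 7.88 at week 4 and 6.99 at week 12, which an exchange leaves unexplained; ELOVL6 and LEP run the way an exchange would give, 9.83 and 12.57 on the array labelled control dog 9 against 3.19 and 10.45 on that labelled ad libitum dog 5.

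The third pattern is the difference between the feeding groups at week 24. Muscle on 2 control arrays as the whole cause is argued against by the 1238 called differences without the 10 arrays, which kept a median of 0.916 of their size (quartiles 0.811 to 1.01; median size 1.15 before and 1.06 after, SE 0.303 and 0.357). There 58 of the 1238 stayed past the threshold, since the SE grew with fewer arrays, and with the muscle mean as a covariate 1022 did. A difference between the dogs before the feeding change is argued against by the week-0 differences, a median of 0.0628 of those at week 24. RNA quality could account for part and cannot be told apart from feeding, with a median of 0.792 of the size left with actin 3' minus 5' as a covariate (size 0.900, SE 0.334) and 28 of the 1238 still past the threshold; ad libitum feeding itself stays open beside it.

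Splits of the dogs test for chance. At week 24 the labelled split gave 1238 calls. As many were given by 4 of 100 splits, the labelled one included, under 5% but unadjusted over the split tests. The highest other split gave 3357, so chance is not excluded. That split put dog 5 with the controls, and its higher count points to a structure at week 24 in which dog 5 stood with them. At week 8 (323 calls) 2 of 100 splits gave as many, with 4159 for the highest other, a structure beyond the feeding groups. For the feeding effect at week 24 (5 calls), 3 of 100 splits gave as many, with 9 for the highest other.

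A count of 0 is matched by every split, so the splits cannot tell anything there. This holds for the averaged feeding effect and those at weeks 4, 8 and 12, where limma called 0 probe sets (959, 1773, 1966 and 1213 at an unadjusted p under 0.05; 100 of 100 splits each, highest other 597, 201, 1992 and 2053), for the groups at week 0 (0 limma calls, 312 at an unadjusted p under 0.05; 100 of 100, 477) and for the lists at week 8 (0 called by camera; 100 of 100, 15). Chance could not be excluded for the joint test over weeks (3 calls, 5 of 100 splits, highest other 5270), or for the groups at week 4 (3 calls, 5 of 100, 1002) and week 12 (1 call, 26 of 100, 2001). Nor could it for the lists called by camera: 2 lists for the averaged effect (78 of 100 splits, highest other 16), 6 at week 4 (29 of 100, 15), 8 at week 12 (46 of 100, 18) and 6 at week 24 (62 of 100, 18). Counts several times the labelled one point to structure among the dogs other than feeding.

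For the changes from week 0 in ad libitum dogs, the arrays of both weeks were split. Over all splits, under 5% gave as many calls at week 12 (182 calls, 2 of 100, highest other 508) and at week 24 (1084, 1 of 100, 894), and over 5% at week 8 (1527, 6 of 100, 8085). Most of these splits do not part each dog's 2 arrays, so they ignore the pairing by dog. At week 24 they also mix batch 6, which has no term, with other batches, and only the labelled split lines up with it. Chance is therefore not excluded by them. At week 4 (113 calls) 3 of 100 splits gave as many, with 4706 for the highest other, but among the 16 splits that part each dog's 2 arrays 2 did, so chance stays open there. Among these 16 splits, too few to reach 5%, as many were given by 2 at week 8 (highest other 6054), 1 at week 12 (131) and 1 at week 24 (178). The splits with 4706 and 8085 calls point to a structure of the arrays. In control dogs under 5% of all splits gave as many at week 24 (1797 calls, 1 of 35 splits, highest other 3), where the same limits of pairing and batch 6 hold. Chance cannot be excluded at week 4 (1 call, 4 of 35, 9). At week 8 (0 limma calls, 322 at an unadjusted p under 0.05; 35 of 35, 2) and week 12 (0 calls, 4029 at an unadjusted p under 0.05; 35 of 35, 5280) the count of 0 leaves the splits without an answer, and in the 8 splits that part the dogs' arrays as many were given by 2, 8, 8 and 1 at weeks 4, 8, 12 and 24.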

How the results depend on the processing

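The fits without arrays and with covariates were chosen only after the results were seen, and the other alternatives were planned. No call of a named gene reversed its sign in any alternative. Each count below is of probe sets past the threshold, or of gene lists in the feeding effect where so named, and counts of these not given stayed within 1.5 times the reported one.

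Without the 10 arrays with muscle transcripts, the comparison of the groups gave 1 at week 0, 6 at week 4, 1437 at week 8, 0 at week 12 and 64 at week 24. The change in ad libitum dogs gave 40, 93 and 92 at weeks 4, 12 and 24, and that in control dogs 0, 1 and 23. The joint test gave 401, the feeding effect 2 at week 24 and 1 averaged, and gene lists numbered 11 at week 4, 4 at week 8 and 9 averaged. Fewer arrays at weeks 0 and 24 widen the errors there, and for week 8 the cause was not tested. Without the week-8 arrays labelled dog 5 and dog 9, the comparison of the groups gave 11, 50 and 15 at weeks 4, 8 and 12, the change in ad libitum dogs 617 at week 8 and 289 at week 12, the feeding effect 2, 1 and 1 at weeks 4, 8 and 12 and 2 averaged, and gene lists 0 at week 12 and 1 averaged. Without both sets, the comparison of the groups gave 1, 7, 134, 10 and 88 at weeks 0 to 24, the change in ad libitum dogs 36 at week 4 and 117 at week 24, that in control dogs 0 at week 4 and 15 at week 24, the feeding effect 1 at week 8, 2 at week 24 and 1 averaged, and gene lists 12, 4 and 1 at weeks 4, 8 and 12 and 9 averaged.

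With actin 3' minus 5' as a covariate, the comparison of the groups gave 2 at week 8 and 29 at week 24, the change in ad libitum dogs 278 at week 8, that in control dogs 8 at week 24 and the feeding effect 1 at week 24, the cause of which was not tested. With the muscle score as a covariate the change in control dogs gave 0 at week 4.

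With no filter, which tests 42924 probe sets, the comparison of the groups gave 6, 3 and 0 at weeks 4, 8 and 12, the change in ad libitum dogs 61, 580, 78 and 643 at weeks 4 to 24, that in control dogs 6 at week 4, the joint test 8, the feeding effect 9 at week 24 and gene lists 4 averaged. With the stricter filter the comparison of the groups gave 0, 822 and 0 at weeks 4, 8 and 12, and the joint test and the feeding effect at week 24 gave 0 limma calls. With no batch term the comparison of the groups gave 388 at week 4 and 1 at week 8, the change in ad libitum dogs 293, 2586 and 314 at weeks 4, 8 and 12, that in control dogs 2 at weeks 4 and 12, the joint test 5, the feeding effect 4 at week 4, and gene lists 3 at week 4 and 1 averaged. At week 4 the groups shared no batch, so without the term a batch difference enters the comparison.

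With a fixed replicate block for the dog the feeding effect at week 24 gave 16, the joint test 9, the change in ad libitum dogs 195 at week 4 and 944 at week 8, and gene lists 0 at week 12; it was not run for the direct comparisons, where the dog and the feeding group coincide. With no replicate block no count moved by over 1.5 times (1236 for the groups and 5 for the feeding effect at week 24), nor did the trended and robust prior move one by as much.

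Quantile normalized again, the change in control dogs gave 2 at weeks 4 and 12. With each array centred on its median, which moved the median of all probe sets by up to 0.103, the comparison of the groups gave 625 at week 8 and 2 at week 12, and the change in control dogs 2 at week 4. This centring moved the split of higher and lower calls from 854 and 384 to 590 and 425 at week 24, from 66 and 257 to 199 and 426 at week 8, and from 659 and 868 to 909 and 766 for the change in ad libitum dogs at week 8. With only the arrays of the weeks compared, which leaves fewer degrees of freedom, the comparison of the groups gave 27, 0, 0 and 48 at weeks 4 to 24, the change in ad libitum dogs 8, 0, 1 and 220, that in control dogs 0 at weeks 4 and 24, the feeding effect 1 at week 12 and 0 at week 24, and gene lists 3 at week 12. This was not run for the averaged effect or the joint test, which use each week. With camera's estimated correlation gene lists numbered 0 averaged and at weeks 4, 12 and 24, and with the mean over all probe sets of a gene 4 averaged. Where no cause is given, the cause was not tested.

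Leaving out each dog in turn, the comparison of the groups ranged from 0 to 0 at week 0, from 0 (without dog 3) to 12 (dog 1) at week 4, from 0 (dog 2) to 2067 (dog 7) at week 8, from 0 (dog 2) to 7 (dog 1) at week 12 and from 238 (dog 2) to 3097 (dog 5) at week 24. The feeding effect ranged from 0 to 6 (dog 8) averaged, 0 to 2 (dog 1) at week 4, 0 to 1324 (dog 8) at week 8, 0 to 1 (dog 1) at week 12 and 0 (dog 2) to 28 (dog 8) at week 24, and the joint test from 0 (dog 4) to 2502 (dog 1). The change in ad libitum dogs ranged from 23 (dog 5) to 1966 (dog 8) at week 4, 12 (dog 2) to 5814 (dog 8) at week 8, 2 (dog 6) to 406 (dog 8) at week 12 and 91 (dog 6) to 1312 (dog 1) at week 24. That in control dogs ranged from 0 (dog 3) to 2540 (dog 1) at week 4, 0 to 0 at week 8, 0 to 4121 (dog 1) at week 12 and 140 (dog 3) to 2308 (dog 8) at week 24. Gene lists ranged from 1 (dog 8) to 15 (dog 3) averaged, 2 (dog 1) to 19 (dog 3) at week 4, 0 to 10 (dog 3) at week 8, 0 (dog 1) to 16 (dog 3) at week 12 and 6 (dog 7) to 10 (dog 5) at week 24. Among lists in the other comparisons, the groups ranged from 3 (dog 1) to 18 (dog 3) at week 0, 1 (dog 1) to 13 (dog 3) at week 4, 0 to 0 at week 8, 0 (dog 1) to 11 (dog 2) at week 12 and 9 (dog 3) to 14 (dog 6) at week 24. For the change in ad libitum dogs they ranged from 0 (dog 8) to 11 (dog 4) at week 4, 0 to 2 (dog 6) at week 8, 10 (dog 8) to 20 (dog 9) at week 12 and 2 (dog 5) to 5 (dog 2) at week 24. For that in control dogs they ranged from 1 (dog 1) to 11 (dog 3), 6 (dog 4) to 12 (dog 3), 4 (dog 5) to 6 (dog 2) and 7 (dog 3) to 13 (dog 4) at weeks 4 to 24. Apart from these lists, other omissions that moved a count by over 1.5 times were these. For the groups at week 4 the count was 0 without dogs 8 or 9, 1 without dogs 5 or 6 and 5 without dog 7, and at week 12 it was 0 without dogs 3, 6 or 9, 2 without dogs 4 or 5 and 3 without dog 7. The feeding effect gave 2 without dog 4 and 1 without dog 5 averaged, 1 without dogs 5 or 7 at week 4, 1 without dogs 1 or 5 at week 8 and 1 without dog 5 at week 12. The change in control dogs gave 0 without dog 9 and 2 without dog 2 at week 4, and 2 without dog 8 at week 12. Gene lists numbered 5 without dog 6 and 4 without dog 9 averaged. At week 8 they numbered 4 without dogs 2 or 5, 2 without dog 4 and 1 without dogs 7, 8 or 9. At week 12 they numbered 0 without dog 5, 4 without dog 7, 5 without dog 4 and 13 without dog 6. For the groups at week 24 the count was 686 without dog 3, 406 without dog 4, 525 without dog 6 and 505 without dog 7. At week 8 it was 0 without dogs 3, 4, 6 or 9, 12 without dog 5, 1402 without dog 8 and 1523 without dog 1. For the change in ad libitum dogs at week 4 it was 30 without dog 2, 37 without dog 6, 27 without dog 7 and 63 without dog 9. At week 8 it was 43 without dog 5, 114 without dog 6, 372 without dog 9, 738 without dog 4, 941 without dog 7 and 949 without dog 3. At week 12 it was 65 without dog 2, 73 without dog 5, 52 without dog 7 and 92 without dog 9, and at week 24 it was 672 without dog 5, 227 without dog 7 and 546 without dog 8. For control dogs at week 24 it was 1178 without dog 1, 1186 without dog 6 and 384 without dog 9. For the feeding effect at week 24 it was 0 without dogs 4 or 9, 1 without dog 3, 2 without dogs 1 or 6 and 3 without dogs 5 or 7, and for the joint test 1 without dogs 2 or 9, 155 without dog 5, 79 without dog 7 and 76 without dog 8. Where the reported fits gave 0 limma calls, 312 to 4029 probe sets had an unadjusted p under 0.05. Signal over background limits the tests to 22690 of 42924 probe sets.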

Other observations

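The genes in this part and their tests were chosen only after their values were seen. At week 24 IGF1, IGF1R and SOCS2 differed between 5 ad libitum and 4 control dogs. The gene list for the steroid hormone and growth hormone axis had a mean of -0.10 and was not past the threshold, so the axis as a whole was not called. IGF1 was higher (1.22, SE 0.358, adjusted p = 0.0393), while its receptor IGF1R (-1.44, SE 0.417, adjusted p = 0.0371) and SOCS2, a feedback brake on the growth hormone receptor (-1.43, SE 0.380, adjusted p = 0.0239), were lower, like CISH (-2.12), each in 5 of 5 ad libitum dogs. The growth hormone receptor GHR itself had values of 0.03 and 0.11 at its 2 probe sets (adjusted p = 0.978 and 0.907). These genes were not past the threshold without the arrays with muscle, with IGF1 at 1.29 (adjusted p = 0.128), IGF1R at -1.57 (adjusted p = 0.234) and SOCS2 at -1.35 (adjusted p = 0.156). The same held with actin 3' minus 5' as a covariate, where IGF1R stood at -0.80 (adjusted p = 0.544), IGF1 at 1.16 (adjusted p = 0.293) and SOCS2 at -1.62 (adjusted p = 0.145).

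ARNTL, ARNTL2 and NR1D2, 3 clock genes, differed at week 24, while the circadian clock list had a mean of 0.12 and was not past the threshold. ARNTL, which drives the clock, was lower (-2.03), whereas its relative ARNTL2 (2.75, SE 0.721, adjusted p = 0.0219) and the repressor NR1D2 (1.11, SE 0.309, adjusted p = 0.0306) were higher, each in 5 of 5 ad libitum dogs. Other probe sets of ARNTL stood at -1.80 (adjusted p = 0.0328) and -1.38 (adjusted p = 0.128), and another of NR1D2 at 1.05 (adjusted p = 0.218). PER1 (-0.23, adjusted p = 0.760), PER2 (0.07, adjusted p = 0.879) and CRY1 (-0.36, adjusted p = 0.556) were not past the threshold. In the fit without the arrays with muscle ARNTL stood at -1.94 (adjusted p = 0.216), ARNTL2 at 2.77 (adjusted p = 0.156) and NR1D2 at 1.22 (adjusted p = 0.158), and with actin 3' minus 5' as a covariate at -2.34, 2.58 and 1.36 (adjusted p = 0.149, 0.224 and 0.121). The hour of sampling is not given in the sources used here.

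No 2 of the 45 arrays were identical, and the highest correlation between arrays, across probe sets, was 0.982, for control dog 1 at weeks 4 and 8. Mean actin 3' minus 5' values were 2.78, 3.42, 1.80, 1.77, 2.05 and 4.08 in batches 1 to 6.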
